A study of Mus musculus with 4 samples.

How the data were processed

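RNA from 4 populations of myeloid cells of the mouse large-intestinal lamina propria was measured on Affymetrix 3' arrays with biotin label, 1 array per population, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set, which the authors made with MAS5, per the submitters' processing notes; its version is not given in the sources used here. In the values themselves the mean over each array, with 2% trimmed from each end, was 500 in all 4 arrays and the lowest value was 1, so each array carried the authors' scaling to a common trimmed mean. Detection calls and scanner images were not used here. The signals were kept on the authors' scale with no further normalization, centring or background step. Signal medians over all probe sets were 109.7 in the CX3CR1high macrophages, 110.2 in the CD11b+ cells, 88.5 in the DCs and 103 in the CX3CR1- cells.

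Of 22690 probe sets, 64 were controls, 20380 named exactly 1 gene, 691 named several and 1555 named none in the platform's probe table, and only those naming 1 gene were used. Gene identifiers were looked up in the mouse gene annotation by their Entrez number, where 96.6% were found, and 0 symbols changed. Genome positions are not given, since a 3' array measures transcripts and no genome build was used here. For each of 12393 genes the probe set with the highest mean log2 signal over the 4 arrays was taken, preferring sets that do not end in _x_at. Spic has 2 probe sets, and both are given.

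A floor was set at the median of all non-control probe sets pooled over the 4 arrays, a signal of 103, and lower signals were set to it. A ratio with 1 side under the floor is a lower bound, written as at least N-fold, and with both sides under the floor there is no ratio. A gene was called higher or lower at 4-fold or more, and a list member at 2-fold or more, with list counts given over the members that have a ratio. With 1 array per population no test, p-value or standard error can be had, and the number of arrays limits the precision of each ratio. As the only spread at hand, the SD of log2 ratios between probe sets of the same gene was taken within each pair of arrays. It holds no difference between animals, collections or hybridisations.

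The comparisons were CX3CR1high macrophages against each of the 3 other populations, the 3 other pairs, and the genes at least 4-fold above or below all 3 other populations. Groups were taken from the labels. In all, 27 lists with 351 genes were used: gate genes, tissue macrophage, heme and iron handling, efferocytosis and scavenger receptors, lysosome, lipid efflux and storage, IL-10 response and negative regulators of TLR signalling, pro-inflammatory cytokines and chemokines, Toll-like receptors, MHC class II, CD103-type DC, shared conventional DC, mature or migratory DC, retinoic acid and TGF-beta, and monocyte. Markers of other cells were those of neutrophils, eosinophils, mast cells, plasmacytoid DC, B and plasma cells, T, NK and innate lymphoid cells, epithelium, and fibroblasts, muscle and endothelium. Cell cycle, type I interferon response, immediate early and reference genes were the last lists. No single-gene probe set named 44 of the listed genes, which were not measured here. Each list's median log2 ratio, with bounds at their bound, was placed among 10000 random lists of the same size matched on mean log2 signal in 20 bins. A list outside the central 95% of these is called above or below the random range, as a description of these arrays and not as a test over animals.

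Named genes follow a rule. They are Spic, the gate genes and any list member, and in each main comparison and direction the 6 largest ratios measured on both sides and the 6 largest bounds. For genes set apart from all other populations the 10 furthest above are named, and the 5 furthest below for the CX3CR1high macrophages. In the other pairs the 3 largest per direction are named. Genes with another probe set of opposite sign, and Riken or predicted names, were passed over. Groups, comparisons, floor, limits, lists, the naming rule and 8 alternatives were set before the data were examined. The alternatives were a floor at the pooled 25th or 75th percentile, no floor, a pseudocount at the pooled 25th percentile, quantile normalization, equal medians, the mean over a gene's probe sets, and leaving out probe sets of the shared types (_s_at, _x_at and _a_at). The other Spic probe set and leaving out the DC array were added after the data were seen.

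The procedure was tested on simulated data. In each main comparison the other array was replaced by the log2 signals of the CX3CR1high array plus noise. The noise had the size of the spread between probe sets within arrays, and 200 of 12393 genes were changed. No unchanged gene was called in any of the 3 main comparisons, genes changed by 2-fold were never called, and at least 98.5% of those changed by 8-fold were. The noise (SD 0.33 to 0.42) is small beside the call limit of 2 log2 units, so the lack of false calls was largely fixed beforehand. It holds no difference between animals, collections or hybridisations. Changed genes lay above the floor and were raised, never lowered, so losses at the floor were not tested. Of 200 random lists of 12 genes, 6% fell outside the random range with no shift and 99.5% with a shift of 1 log2 unit. These lists were drawn from the same genes as the random range, so the rate with no shift was largely fixed beforehand. Members of the real lists may vary together, which this check leaves out. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.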

Results

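Gene expression was measured in 4 populations of myeloid cells from the lamina propria, the connective tissue under the epithelium, of the large intestine of C57BL/6J mice. The populations were told apart by surface markers. CX3CR1high macrophages carried CD11c, CD11b and a high level of the fractalkine receptor CX3CR1, and CX3CR1- cells carried CD11c and CD11b without CX3CR1. CD11b+ cells carried CD11b without CD11c, and CD11chigh dendritic cells (DCs) carried much CD11c without CD11b. The sample title of the CX3CR1- cells also calls them DC, but here DCs means the CD11chigh population only. Each population was hybridised to 1 Affymetrix 3' array of 22690 probe sets, read here as 12393 genes. Values are signals in linear intensity units, scaled by the authors to the same trimmed mean on every array. Median signals over all probe sets were 109.7 in the CX3CR1high macrophages, 110.2 in the CD11b+ cells, 88.5 in the DCs and 103 in the CX3CR1- cells. In the same order, 57.2%, 56.9%, 52.7% and 55.8% of genes reached the floor, the pooled median signal of 103. The ratio of 3' over 5' control signals, which grows as RNA is less intact, was 1.08, 2.17, 0.791 and 3.40 for Gapdh and 1.68, 3.18, 1.115 and 2.76 for Actb, again in this order. With 1 array per population there were no replicates and no test, and the number of arrays limits the precision of every ratio. Between probe sets of the same gene on the same arrays the SD of log2 ratios was 0.33, 0.39 and 0.42 in the 3 main comparisons, which leaves out differences between mice and between collections.

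The labels set the series on Spic in CX3CR1high macrophages of the intestine. Spic is an ETS-family transcription factor needed for the iron-recycling red pulp macrophages of the spleen. It had its highest signal in the CX3CR1high macrophages, 936, against 239 in the CD11b+ cells, 102 in the CX3CR1- cells and 29.2 in the DCs. The ratio over the CD11b+ cells was 3.93-fold, just under the 4-fold limit for a call. Over the CX3CR1- cells and the DCs, where Spic lay under the floor, the ratio was at least 9.10-fold. A second Spic probe set gave signals of 2163, 464, 176 and 87.1 in the same order. Its ratios were 4.66-fold over the CD11b+ cells, 12.3-fold over the CX3CR1- cells and at least 21.0-fold over the DCs. Both probe sets are of types that can match more than 1 transcript.

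The genes of the surface markers were compared next. Cx3cr1 had a signal of 1499 in the CX3CR1high macrophages. That was 2.35-fold the signal of the CD11b+ cells (638), 5.15-fold that of the CX3CR1- cells (291) and at least 14.6-fold that of the DCs (65.2). Itgam, which encodes CD11b, was under the floor in the DCs (45.9). It stood at 691 in the CX3CR1high macrophages, 514 in the CD11b+ cells and 408 in the CX3CR1- cells. Itgax, which encodes CD11c, was highest in the CX3CR1- cells (8412) and the DCs (5893). Its signal in the CD11b+ cells, which were gated as CD11c-negative, was 1864, near that of the CX3CR1high macrophages (1826). Itgae, which encodes CD103, reached 4962 in the DCs and 374 in the CX3CR1- cells and was under the floor in both others. As a list, these 4 gate genes lay within the range of random lists in each main comparison. Their median log2 ratios were 0.43 over the CD11b+ cells, 0.53 over the DCs and -0.55 over the CX3CR1- cells.

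**Figure D1:**
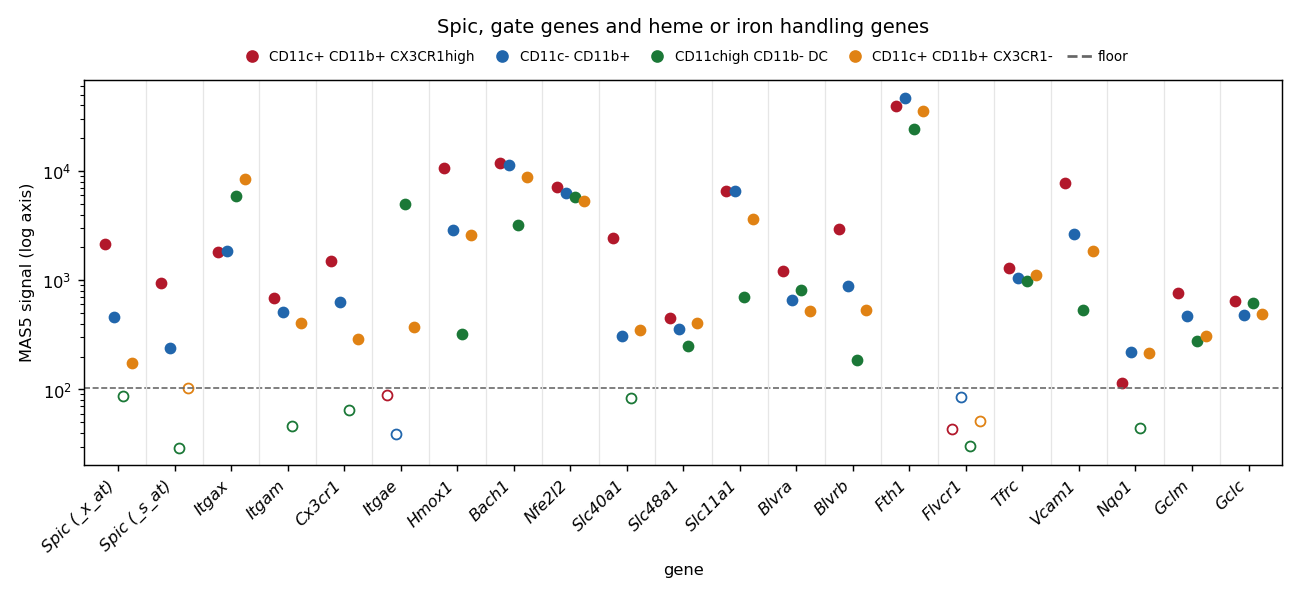
Signals (log axis) of both Spic probe sets, the gate genes and the heme and iron handling genes, 1 point per array in 4 colours, with open points under the floor (dashed line). Spic, Cx3cr1, Hmox1, Slc40a1, Blvrb and Vcam1 are highest in the CX3CR1high macrophages, and Itgae in the DCs.

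Against the CD11b+ cells, the CX3CR1high macrophages had higher signals for tissue macrophage genes and for part of the heme and iron handling genes, and lower signals for monocyte genes. In the tissue macrophage list 8 of 15 members were higher and 0 lower, with a median log2 ratio of 1.03. Hpgds, a prostaglandin D synthase, was 6.18-fold higher (913 against 148). Cd163, the scavenger receptor for hemoglobin bound to haptoglobin, was 3.75-fold higher (6566 against 1752), and the anti-inflammatory cytokine Il10 2.76-fold (7028 against 2548). In the heme and iron handling list 5 of 15 members were higher and 0 lower, with a median log2 ratio of 0.43. The 5 were Spic, the iron exporter Slc40a1 (7.90-fold), heme oxygenase Hmox1 (3.77-fold), biliverdin reductase Blvrb (3.33-fold) and the adhesion molecule Vcam1 (2.95-fold). Hmox1 stood at 10772 against 2861 and Slc40a1 at 2422 against 306. The ferritin gene Fth1 (39180.1 against 47022) and the heme-responsive repressor Bach1 (11784 against 11283) were within 2-fold. Fth1 lay near the highest signal of the CX3CR1high array (44238), which limits how far its ratio can reach. In the monocyte list 0 of 10 members were higher and 8 lower, with a median log2 ratio of -2.28. Chil3 was 16.6-fold lower (798 against 13237), S100a4 7.68-fold and the proteoglycan Vcan 5.70-fold. The chemokine receptor Ccr2, which lets monocytes leave the bone marrow, was 5.52-fold lower (269 against 1482).

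Phagocyte and cytokine lists were also above the range of random lists over the CD11b+ cells. The efferocytosis and scavenger receptor list had 3 of 10 members higher and 1 lower (median 0.60), with Cd36 3.28-fold and Stab1 2.52-fold higher and Mfge8 lower. The lipid efflux and storage list had 2 of 11 members higher and 0 lower (median 0.31), which were Gpnmb (6.14-fold) and Trem2 (3.14-fold). The lysosome list had 1 of 12 members higher and 0 lower (median 0.29), the protease Ctsl, and the type I interferon list 2 of 9 members higher and 0 lower (median 0.92), Oasl1 and Ifit2. The pro-inflammatory cytokine and chemokine list had 5 of 15 members higher and 1 lower (median 0.45). Its higher members were the monocyte attractants Ccl7 (4.90-fold) and Ccl2 (3.41-fold), Ccl4, Ccl3 and Tnf (2.10-fold), and Il6 was 2.13-fold lower. Markers of epithelial cells stood beside these lists, with 12 of 12 members higher and 0 lower (median 2.39). The keratin Krt8 was at 6182 against 932, and the carbonic anhydrase Car1 at 2200.5 against 317. Below the range were also lists of other blood cells. The neutrophil list had 0 of 10 members higher and 5 lower (median -0.72). S100a9 was 7.53-fold and S100a8 6.24-fold lower. The eosinophil list had 0 of 3 members higher and 1 lower (median -0.98), all 3 as bounds. The mast cell list had 0 of 2 members higher and 1 lower (median -1.59), which was Hdc, the enzyme that makes histamine (8.06-fold), and 8 of its 10 members were under the floor in both arrays. The retinoic acid and TGF-beta list was below the range too, with 0 of 7 members higher and 2 lower (median -0.76). The fibroblast, muscle and endothelial list was within the range, with 0 of 14 members higher and 6 lower (median -0.32), but its 6 lower members were all fibroblast genes, such as the collagen Col3a1 at 6261 against 28325. Median log2 ratios of the other lists within the range were -0.13 for IL-10 response and TLR regulators, 0.11 for Toll-like receptors and 0.18 for MHC class II. They were 0.45 for CD103-type DC, 0.27 for shared conventional DC, 0.24 for migratory DC and -0.08 for plasmacytoid DC genes. B and plasma cell (-0.48), T and NK cell (0.12), cell cycle (0.09), immediate early (-0.17) and reference genes (-0.24) completed these lists.

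Among 7512 genes with a ratio, 65 were at least 4-fold higher and 60 at least 4-fold lower in the CX3CR1high macrophages than in the CD11b+ cells. Lypd8 (11122 against 444), Muc3 (14.7-fold) and Phgr1 (10.3-fold), which are known from intestinal epithelium, had the largest ratios measured on both sides. Npl (9.52-fold), Dmbt1 (9.24-fold) and the chemokine Ccl8 (8.54-fold, 19869 against 2326) came next. The largest lower bounds were those of the serum amyloid Saa1 (at least 69.3-fold, 7125 against 70.2), Sycn, the carbonic anhydrase Car4 (at least 30.9-fold), the water channel Aqp8 (at least 11.5-fold), Ckmt1 and Fxyd4. In the other direction, Chil3, the receptor Cd300lf (8.80-fold), Hdc, Ltb (7.94-fold), S100a4 and S100a9 led the measured ratios. Haptoglobin Hp (at least 17.0-fold) led the bounds, before the matrix genes Mfap4 and Prelp, and Alox15, Nfe2 and Dna2. Of 55 further probe sets of the called genes, 41 differed at least 2-fold the same way and 0 the opposite way. The Gapdh ratio of 3' over 5' control signals was 1.08 in the CX3CR1high macrophages and 2.17 in the CD11b+ cells. Counts ran from 22 higher and 27 lower with the floor at the 75th percentile to 606 and 634 with none. The lysosome, lipid and neutrophil lists came to lie within the random range without shared probe sets, the lipid list also with no floor, the neutrophil, retinoic acid and eosinophil lists with the higher floor, and the mast cell list with the lower one.

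**Figure D2:**
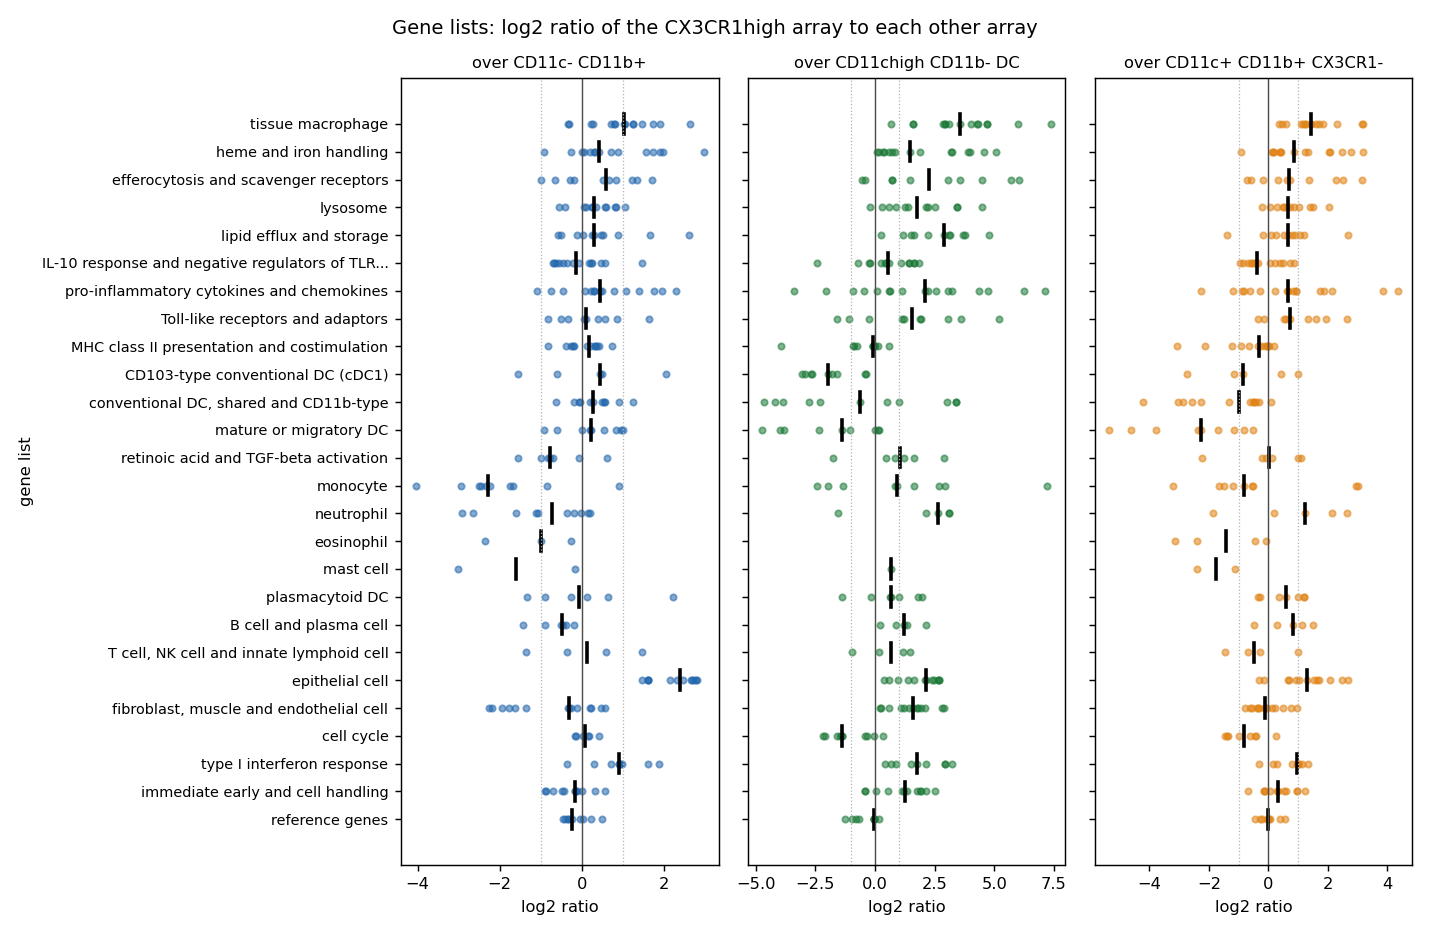
Log2 ratios of list members in the CX3CR1high macrophages over each other population, 1 panel per comparison and 1 point per gene, with black bars at list medians and dotted lines at 2-fold. The tissue macrophage, heme and iron handling and epithelial medians lie above 0 in every panel, and the monocyte median over the CD11b+ cells is -2.28.

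Against the CD11chigh DCs, most tissue macrophage genes and part of the heme handling genes were higher in the CX3CR1high macrophages, and most CD103-type and migratory DC genes were lower. In the tissue macrophage list 14 of 15 members were higher and 0 lower, with a median log2 ratio of 3.55. The mannose receptor Mrc1 was at least 167-fold higher (17169 against 97.8), Il10 26.3-fold (7028 against 267) and the complement gene C1qc 25.9-fold. In the heme and iron handling list 8 of 15 members were higher and 0 lower, with a median log2 ratio of 1.47. Hmox1 was 33.8-fold higher (10772 against 319), Slc40a1 at least 23.5-fold and Blvrb 15.9-fold. In the CD103-type DC list 0 of 9 members were higher and 7 lower, with a median log2 ratio of -1.98. The chemokine receptor Xcr1 was at least 6.40-fold lower (28.7 against 658), Cd24a 8.36-fold and the transcription factor Irf8 3.48-fold (3272 against 11382). Of the mature or migratory DC genes, 0 of 9 members were higher and 6 lower, with a median log2 ratio of -1.40. Ccr7, the receptor that leads DCs to lymph nodes, was 14.1-fold lower (576 against 8091), and the chemokines Ccl17 and Ccl22 were 26.3-fold and 15.8-fold lower.

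Further phagocyte lists were above the range of random lists over the DCs. The efferocytosis and scavenger receptor list had 6 of 10 members higher and 0 lower (median 2.26). The lysosome list had 8 of 12 members higher and 0 lower (median 1.76), with the protease Ctsd 22.3-fold higher, and the lipid efflux and storage list 10 of 11 members higher and 0 lower (median 2.89), with the sterol exporter Abca1 27.6-fold higher. Toll-like receptors had 7 of 10 members higher and 2 lower (median 1.54). Tlr2 was 37.3-fold higher, and Tlr3 stood at 84.9 against 309. The pro-inflammatory cytokine and chemokine list had 10 of 17 members higher and 2 lower (median 2.09). Ccl7 (139-fold), Ccl2 (75.3-fold) and Tnf (at least 26.6-fold) were among the higher members. Il12b, a subunit of interleukins 12 and 23, was at least 10.4-fold lower (68.0 against 1066), and Cxcl9 4.19-fold lower. The interferon response list had 6 of 9 members higher and 0 lower (median 1.76), and the immediate early list, which also answers to handling of cells, 8 of 12 members higher and 0 lower (median 1.28).

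Some lists of other cells were also above the random range over the DCs. Epithelial markers had 9 of 12 members higher and 0 lower (median 2.13), and the fibroblast, muscle and endothelial list 10 of 13 members higher and 0 lower (median 1.61). The monocyte list had 4 of 9 members higher and 3 lower (median 0.94), the neutrophil list 4 of 5 members higher and 1 lower (median 2.66) and the B and plasma cell list 3 of 5 members higher and 0 lower (median 1.23). Below the range lay the shared conventional DC list, with 3 of 11 members higher and 5 lower (median -0.63). Its growth factor receptors Flt3 and Kit were at least 25.1-fold and at least 18.4-fold lower, the transcription factor Zbtb46 was 6.88-fold lower, and Sirpa was 10.4-fold higher. The cell cycle list was below it with 0 of 10 members higher and 6 lower (median -1.37). Within the range, median log2 ratios were -0.07 for MHC class II, 0.53 for IL-10 response and TLR regulators and 1.03 for retinoic acid and TGF-beta. They were 0.69 for plasmacytoid DC, 0.68 for T and NK cell, 0.69 for the single measured mast cell gene, Hdc, and -0.06 for reference genes. All 6 eosinophil genes were under the floor in both arrays and had no ratio. MHC class II genes such as H2-Aa (31256 and 33046) lay near the highest signals of the arrays (44238 and 38968), which limits how far their ratios can reach.

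Of 7480 genes with a ratio, 453 were at least 4-fold higher and 146 at least 4-fold lower in the CX3CR1high macrophages than in the DCs. The median of the DC array over all probe sets was lower by 0.31 log2 units, and with equal medians the counts were 341 and 223. Among genes with a ratio, however, the median log2 ratio was 0.02 on the authors' scale and -0.27 with equal medians. The Gapdh ratio of 3' over 5' control signals was 1.08 against 0.791. Ratios measured on both sides were largest for the chemokines Ccl7, Ccl8 (122-fold, 19869 against 163) and Ccl2, then Pf4 (66.6-fold), Ccl9 (49.0-fold) and Pmp22 (42.2-fold). Lower bounds were largest for Mrc1, the coagulation factor F13a1 (at least 148-fold), Retnla (at least 116-fold), Cd93 (at least 73.2-fold), Cbr2 (at least 70.7-fold) and Saa1 (at least 69.3-fold). Among lower genes, the actin-severing protein Scin (36.3-fold, 109 against 3938), Serpinb6b (31.5-fold), the lectin-like receptor Klrk1 (28.0-fold), Ccl17, Hepacam2 (25.3-fold) and Rtl8c (19.6-fold) had the largest measured ratios, apart from Plet1 (33.3-fold), which the naming rule passes over because another of its probe sets differed the opposite way. Itgae (at least 48.2-fold), Flt3, Septin6 (at least 23.2-fold), Kit, Gpr33 and Lrrk2 had the largest bounds. Further probe sets of the called genes numbered 321, of which 271 differed at least 2-fold the same way and 0 the opposite way. Counts were 178 higher and 74 lower with the floor at the 75th percentile and 1368 and 680 with none. The shared conventional DC list came to lie within the random range under both rescalings and without shared probe sets, the neutrophil and B and plasma cell lists under every other floor, the monocyte list with the higher floor and without shared probe sets, and the cell cycle list with the higher floor.

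Against the CX3CR1- cells, which share CD11c and CD11b with them, the CX3CR1high macrophages again had higher signals for most tissue macrophage genes and part of the heme handling genes, and lower signals for most migratory DC genes and part of the other DC genes. In the tissue macrophage list 12 of 15 members were higher and 0 lower, with a median log2 ratio of 1.42. Hpgds was at least 8.87-fold higher, Cd163 9.15-fold (6566 against 718) and the Fc receptor Fcgr1 3.28-fold, and Mrc1 stood at 17169 against 3436. In the heme and iron handling list 7 of 15 members were higher and 0 lower, with a median log2 ratio of 0.85. Slc40a1 was 6.84-fold higher (2422 against 354), Blvrb 5.57-fold, Vcam1 4.25-fold and Hmox1 4.15-fold (10772 against 2595). Of the mature or migratory DC genes, 0 of 9 members were higher and 7 lower, with a median log2 ratio of -2.27. Ccl22 was 40.5-fold lower (393 against 15935), Ccl17 24.6-fold, Ccr7 13.8-fold (576 against 7927) and the actin-bundling protein Fscn1 4.82-fold. In the shared conventional DC list 0 of 12 members were higher and 6 lower, with a median log2 ratio of -0.97. Kit was at least 18.6-fold lower, Flt3 at least 8.13-fold, Zbtb46 7.28-fold and the lectin Cd209a 4.80-fold (542 against 2603). The CD103-type DC list was also below the random range, with 1 of 5 members higher and 2 lower (median -0.86), Irf8 being the higher one, and its other 4 members on the array, among them Xcr1, were under the floor in both arrays.

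Phagocyte lists were above the random range over the CX3CR1- cells too. The efferocytosis and scavenger receptor list had 4 of 10 members higher and 0 lower (median 0.68), with Gas6 8.84-fold and Stab1 5.69-fold higher. The lysosome list had 4 of 12 members higher and 0 lower (median 0.68), and the lipid efflux and storage list 3 of 11 members higher and 1 lower (median 0.66), with Trem2 6.44-fold higher and the lipase Lpl 2.61-fold lower. Toll-like receptors had 4 of 9 members higher and 0 lower (median 0.73), with Tlr7 6.29-fold and Tlr2 3.82-fold higher. The pro-inflammatory cytokine and chemokine list had 5 of 17 members higher and 2 lower (median 0.66). Ccl7 and Ccl2 were 20.6-fold and 14.5-fold higher, and Il12b and Ccl5 were at least 4.82-fold and 2.26-fold lower. The interferon response list had 4 of 9 members higher and 0 lower (median 0.98), and the immediate early list 1 of 12 members higher and 0 lower (median 0.32). Of the lists of other cells, those of epithelium, neutrophils and B and plasma cells were above the range too. The epithelial list had 8 of 13 members higher and 0 lower (median 1.29), with Lgals4 4.18-fold and Car1 3.23-fold higher. The neutrophil list had 3 of 5 members higher and 1 lower (median 1.22), the higher members being S100a8, S100a9 and Csf3r. The B and plasma cell list had 2 of 5 members higher and 0 lower (median 0.84), Ighm and Cd79b, and its median turned negative with the lower floor, with no floor and with the pseudocount.

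Below the random range over the CX3CR1- cells was also the monocyte list, with 2 of 9 members higher and 4 lower (median -0.83). S100a4 was 9.18-fold and fibronectin, Fn1, 3.13-fold lower, while F13a1 was 8.01-fold and Chil3 at least 7.75-fold higher. The eosinophil list had 0 of 4 members higher and 2 lower (median -1.43), Alox15 and Siglecf. The mast cell list had 0 of 2 members higher and 2 lower (median -1.75), Hdc and Gata2, and its other 8 members were under the floor in both arrays. The cell cycle list had 0 of 8 members higher and 3 lower (median -0.80), Mki67, Top2a and Birc5. The MHC class II list was within the range with 0 of 12 members higher and 3 lower (median -0.30), of which H2-Oa was 8.34-fold and the costimulatory molecule Cd80 4.35-fold lower. So was the retinoic acid and TGF-beta list with 2 of 6 members higher and 1 lower (median 0.01), and the retinal dehydrogenase Aldh1a2 was at least 4.73-fold lower. Median log2 ratios of the others within the range were -0.39 for IL-10 response and TLR regulators, 0.60 for plasmacytoid DC, -0.48 for T and NK cell, -0.11 for fibroblast, muscle and endothelial and -0.01 for reference genes.

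Of 7462 genes with a ratio, 103 were at least 4-fold higher and 94 at least 4-fold lower in the CX3CR1high macrophages than in the CX3CR1- cells. Ratios measured on both sides were largest for Car4 (27.8-fold), Ccl8 (22.2-fold), Ccl7, the folate receptor Folr2 (19.4-fold, 7079 against 364), the ficolin Fcna (19.1-fold) and Ccl12 (18.2-fold). The largest bounds were those of Saa1, Aqp8, Spic, the immunoglobulin segment Igkv9-120 (at least 8.94-fold), Hpgds and Chil3. Lower by the largest measured ratios were Ccl22, Ccl17, Nup210 (14.9-fold), Ccr7, Cd300lf (12.7-fold) and the protease Napsa (11.9-fold). Kit, Alpk2 (at least 10.2-fold), Alox15 (at least 8.75-fold), Flt3, Tesc and Klra17 were lower by the largest bounds. Of 85 further probe sets of called genes, 67 differed at least 2-fold the same way and 0 the opposite way. The Gapdh ratio of 3' over 5' control signals was 1.08 against 3.40 in this comparison. With the floor at the 75th percentile the counts were 47 and 37, and with no floor 616 and 649. Without shared probe sets the lipid, shared conventional DC, monocyte, neutrophil and immediate early lists came to lie within the random range, as did the CD103-type DC list with the lower floor or the pseudocount, the neutrophil list under every other floor, the interferon list with the higher floor, and the immediate early list with no floor or the mean over probe sets.

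**Figure D3:**
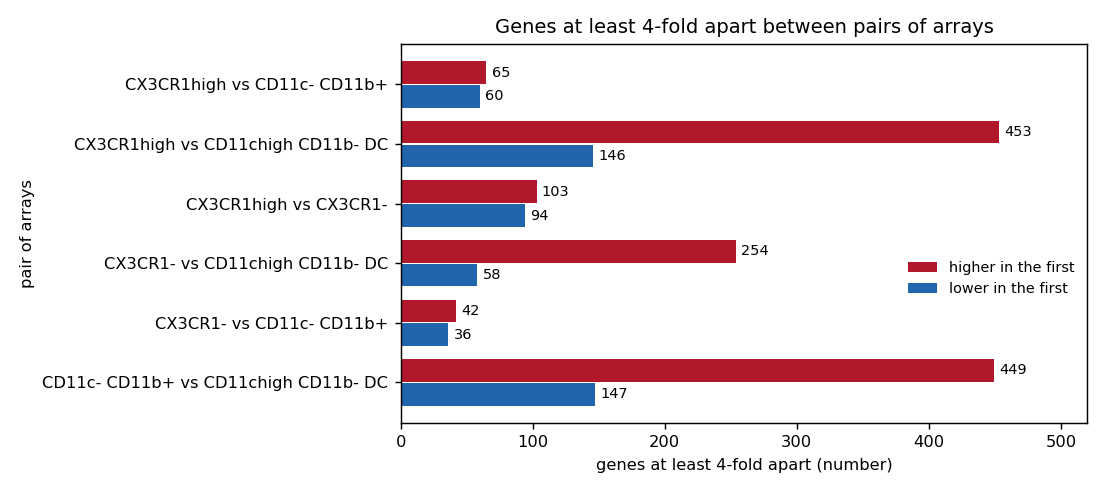
Numbers of genes at least 4-fold higher (red) and lower (blue) in the first of each pair of arrays, as bars from 0. The 3 pairs with the DC array have the most genes, among them 453 higher in the CX3CR1high macrophages and 449 higher in the CD11b+ cells.

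Genes set apart from all 3 other populations at once were counted for each population. In the CX3CR1high macrophages 35 genes were at least 4-fold above every other array and 7 at least 4-fold below. Saa1, Car4, Aqp8, Lypd8, Sycn and Myo15b were among the 10 furthest above, together with Ccl8 (8.54-fold above the next highest), Fcna (7.97-fold), Slc40a1 (6.84-fold) and the lectin Cd209f (6.77-fold). The 5 furthest below were Lsp1, S100a4, Napsa, the integrin subunit Itgb7 (262 against 1126 or more) and Gramd4. Most epithelial markers were also higher in the CX3CR1high macrophages, with medians of 2.39, 2.13 and 1.29 over the CD11b+ cells, DCs and CX3CR1- cells. Whether Lypd8 and other genes known from epithelium came from the macrophages themselves or from epithelial RNA stays open. A second epithelial list, given under the other observations, could not decide on epithelial RNA, and expression by the macrophages was not tested. In the CD11b+ cells 16 genes were above all others, led by Hp, Chil3, S100a9 and S100a8. They included the matrix genes Mfap4, Mgp and Prelp, and Rarres2, Slpi and the eosinophil attractant Ccl11. The 2 genes below all others there were Dnase1l3 (76.8) and Mmp12 (107), named after their values were seen. In the DCs 39 genes stood above all others and 152 below. Rtl8c (19.3-fold above the next highest) and Itgae (13.3-fold) led the higher ones, with Gpr33, Scin, Bcl2l14, Hhex, Ppt1, Nsmaf, Timeless and Qpct. The CX3CR1- cells had 2 genes above all others, the lectins Cd209c (615, at least 5.98-fold) and Cd209a (2603, 4.80-fold). Their single gene below all others was the immunoglobulin light chain segment Iglv1 (431 against 2142 or more), also named after its value was seen. Counts above all others ranged over the other floors from 14 to 111 in the CX3CR1high macrophages and 18 to 115 in the DCs, and those below all others in the DCs from 56 to 577, and with the lower floor more genes were above all others in the CX3CR1high macrophages (67) than in the DCs (51). Without the DC array, an alternative added after the data were seen, the CX3CR1- cells had 31 genes above and 14 below both others, and the CX3CR1high macrophages 38 and 14.

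The 3 remaining pairs compare the other populations among themselves. Over the DCs, tissue macrophage genes were also above the random range in the CX3CR1- cells, with 11 of 15 members higher and 0 lower (median 2.48), as was the heme and iron handling list, with 7 of 14 members higher and 0 lower (median 0.89). The CD103-type DC list was below it, with 0 of 9 members higher and 5 lower (median -1.59). In the CD11b+ cells over the DCs, the tissue macrophage list had 12 of 15 members higher and 0 lower (median 2.77) and the heme and iron handling list 8 of 15 members higher and 0 lower (median 1.09), both above the range. In both populations the scavenger receptor, lysosome, lipid, cytokine, interferon, IL-10 response and immediate early lists were above the range too. So were the Toll-like receptor and retinoic acid lists in the CD11b+ cells. The cell cycle list was below the range in both, and the CD103-type and migratory DC lists in the CD11b+ cells. Some lists of other cells also stood above the range. The fibroblast, muscle and endothelial list had 10 of 13 members higher and 0 lower (median 1.90) in the CX3CR1- cells and 10 of 14 members higher and 0 lower (median 2.44) in the CD11b+ cells. The monocyte list had 5 of 8 members higher and 1 lower (median 1.55) in the CX3CR1- cells and 8 of 10 members higher and 0 lower (median 2.53) in the CD11b+ cells. Neutrophil and mast cell medians, also above the range, were 1.88 and 2.09 in the CX3CR1- cells and 1.35 and 1.94 in the CD11b+ cells. In the CX3CR1- cells they rested on 3 and 2 members with a ratio, 2 and 1 of them bounds. In the CD11b+ cells they rested on 10 and 2 members, 9 and 1 of them bounds. Above the range were also the eosinophil median in the CX3CR1- cells (1.43, 4 members, all bounds) and the B and plasma cell median in the CD11b+ cells (1.61, 6 members). The CX3CR1- cells had 254 genes at least 4-fold higher and 58 lower than the DCs, or 194 and 92 with equal medians. Retnla (at least 269.7-fold, 27748 against 71.9), Ccl9 and Serpinb2 (at least 35.9-fold) had the largest ratios upward, and Rtl8c, Itgae (13.3-fold) and Ctla2b (12.5-fold) downward. Compared with the CD11b+ cells, 42 genes were higher in the CX3CR1- cells and 36 lower, or 46 and 26 with equal medians. In this pair the shared conventional DC list had 8 of 13 members higher and 0 lower (median 1.76), the migratory DC list 8 of 9 members higher and 0 lower (median 1.43) and the CD103-type DC list 3 of 5 members higher and 0 lower (median 1.18), all above the random range. Above it were also the medians of the MHC class II (0.42), cell cycle (1.02), epithelial (1.03), eosinophil (0.61) and gate genes (0.76). The tissue macrophage list had 0 of 15 members higher and 2 lower (median -0.52), the heme and iron handling list 0 of 15 members higher and 1 lower (median -0.35) and the monocyte list 0 of 10 members higher and 5 lower (median -1.36), all below the range. Below it were also the medians of the scavenger receptor (-0.52), lysosome (-0.46), Toll-like receptor (-0.76), retinoic acid (-0.80) and immediate early lists (-0.69). So were those of the neutrophil (-1.09), B and plasma cell (-1.14) and fibroblast, muscle and endothelial lists (-0.36). The DC-associated genes Ccl22 (72.3-fold), Ccl17 (49.3-fold) and Ccr7 (7927 against 397) led the higher genes. Chil3 (at least 129-fold), S100a8 (at least 39.4-fold) and S100a9 (at least 33.2-fold) led the lower ones. The CD11b+ cells had 449 genes higher and 147 lower than the DCs, or 353 and 227 with equal medians. Retnla, Chil3 and F13a1 led the higher genes, and Serpinb6b (56.7-fold), Ccl17 and Itgae the lower ones. Across genes, which are not independent replicates, Pearson's r of log2 signals was 0.937 between CX3CR1- and CD11b+ cells. It was 0.927 between CX3CR1high macrophages and CD11b+ cells and 0.902 between CX3CR1high macrophages and CX3CR1- cells. Between the DCs and the CX3CR1- cells, CD11b+ cells and CX3CR1high macrophages it was 0.868, 0.802 and 0.794.

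Some genes known from epithelium, fibroblasts and plasma cells, among them Krt8, Col3a1 and Igha, had signals above the floor in all 4 arrays. The epithelial genes Epcam and Krt8 stood at 1357 and 6182 in the CX3CR1high macrophages and 443 and 932 in the CD11b+ cells. In the DCs they were at 908 and 1192, and in the CX3CR1- cells at 839 and 2530.4. Fibroblast genes were highest in the CD11b+ cells, where Col3a1 reached 28325 and Dcn 15299. Col3a1 was at 6261 in the CX3CR1high macrophages, 2360.5 in the DCs and 9639 in the CX3CR1- cells. The immunoglobulin A heavy chain Igha had signals of 31732 in the CX3CR1high macrophages, 53324 in the CD11b+ cells, 22258 in the DCs and 28278 in the CX3CR1- cells. The T cell genes Cd3e, Cd3d and Cd3g were under the floor in all 4.

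**Figure D4:**
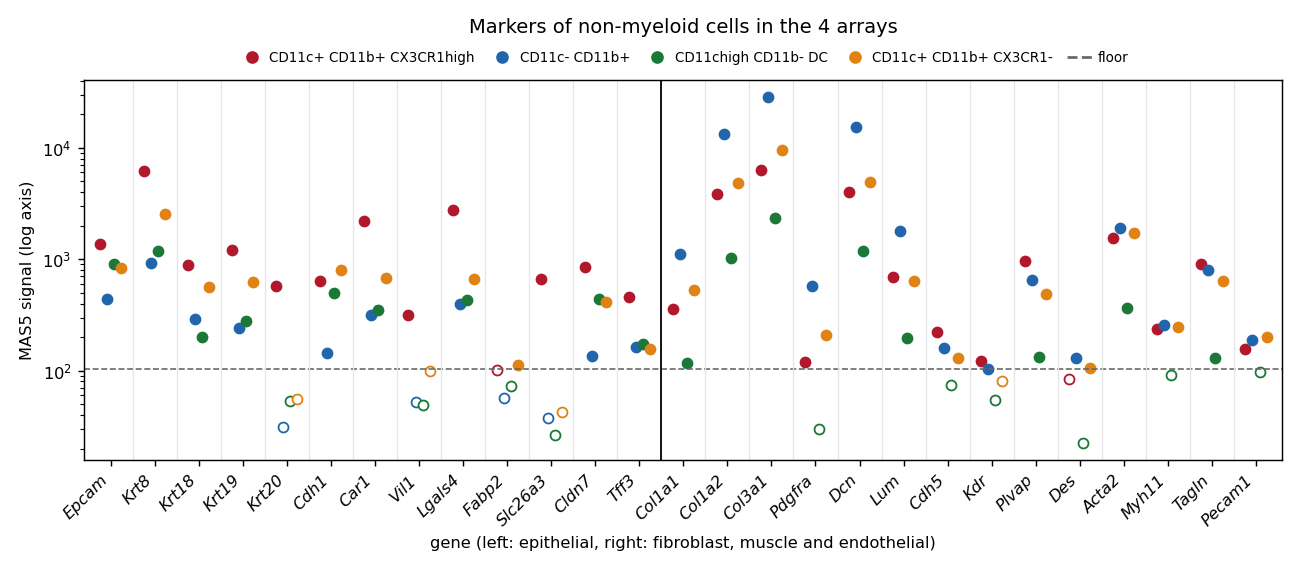
Signals (log axis) of epithelial genes (left) and of fibroblast, muscle and endothelial genes (right), 1 point per array, with open points under the floor (dashed line). Most epithelial genes are highest in the CX3CR1high macrophages and the fibroblast genes in the CD11b+ cells.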

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

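The other Spic probe set and leaving out the DC array were chosen after the data were seen, and every other alternative was planned. No paired analysis was possible because each population has 1 array. A count is called moved when it differs by more than 1.5 times from the value in the report, and a ratio when it moves by more than the spread between probe sets. Spic ratios moved in 9 of 24 cases and reversed in 0, with log2 values from 1.05 to 5.001 in all. Numbers of lists above the random range moved under 0 of 24 alternatives, and numbers below it under 1. Of 636 list medians, 560 kept their place above, within or below the random range. Among lists outside the range in the report, 3 medians reversed. Changes of sign in lists within the range were not counted. Of 6918 ratios of single genes, 645 moved and 0 reversed. A reversal of a single gene was counted only where its ratio in the report was at least 2-fold. The other floors, no floor, the pseudocount and equal medians cannot reverse such a ratio, for Spic or any other gene. The lack of reversals of single genes was thus largely fixed beforehand. Genes without a ratio under an alternative were left out. Counts of genes 4-fold higher moved in 20 of 48 cases and lower in 21 of 48. Numbers above all others moved in 12 of 35 and below all others in 20 of 35. Quantile normalization moved none of these counts. The floor sets which ratios exist and how large a bound can be, so signal over the floor limits these counts by construction. With the lower floor or none, all 65 and 60, 453 and 146, and 103 and 94 genes called over the CD11b+ cells, DCs and CX3CR1- cells kept their call. This follows from the arithmetic, since a lower floor can only keep or enlarge a called ratio. For every other change the cause was not tested.

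With the floor at the pooled 25th percentile, genes higher and lower in the CX3CR1high macrophages were 156 and 112 over the CD11b+ cells, 763 and 227 over the DCs and 174 and 151 over the CX3CR1- cells. They were 452 and 93 for CX3CR1- cells over DCs, 87 and 77 for CX3CR1- over CD11b+ cells and 760 and 248 for CD11b+ cells over DCs. Above all others were 67 genes in the CX3CR1high macrophages, 27 in the CD11b+ cells and 5 in the CX3CR1- cells, and below all others 11, 8 and 4, with 264 in the DCs. The Spic log2 ratio over the DCs was 5.001 against 3.19 in the report, and the B and plasma cell median over the CX3CR1- cells -0.20 against 0.84.

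With the floor at the 75th percentile, the main counts were 22 and 27, 178 and 74, and 47 and 37 in the same order. All of these were among the genes already called, which is certain beforehand, since a higher floor can only keep or shrink a ratio. The other pairs had 89 and 26, 19 and 18, and 169 and 67. Above all others were 14 genes in the CX3CR1high macrophages, 9 in the CD11b+ cells, 18 in the DCs and 1 in the CX3CR1- cells, and below all others 2, 0 and 56 in the first 3. The Spic log2 ratio was 1.05 over each of the 3 other populations, each of which was then under the floor.

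With no floor, the main counts were 606 and 634, 1368 and 680, and 616 and 649, and the other pairs had 1107 and 522, 609 and 568, and 1468 and 734. Above all others were 111, 110, 115 and 70 genes in the CX3CR1high macrophages, CD11b+ cells, DCs and CX3CR1- cells, and below all others 151, 172, 577 and 130. Spic over the DCs was 5.001 and the B and plasma cell median over the CX3CR1- cells -0.20.

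With the pseudocount, 117 genes were higher over the CD11b+ cells and 64 in CX3CR1- over CD11b+ cells. Below all others were 4 in the CX3CR1high macrophages, 5 in the CD11b+ cells and 2 in the CX3CR1- cells. Spic over the DCs was 4.20 and the B and plasma cell median over the CX3CR1- cells -0.14.

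Equal medians shift log2 ratios over the DCs by 0.31 for the CX3CR1high macrophages, 0.32 for the CD11b+ cells and 0.22 for the CX3CR1- cells. Lower genes then numbered 223, 227 and 92 against 146, 147 and 58. With the mean over probe sets, genes below all others were 1 in the CD11b+ cells and 0 in the CX3CR1- cells, and Spic over the DCs was 3.79. Without shared probe sets, 0 genes were below all others in the CX3CR1- cells, and 4 lists in place of 7 were below the random range over them. Spic has no value there, since both its probe sets are of the shared types. The other Spic probe set gave 4.39 over the DCs and 3.62 over the CX3CR1- cells. Without the DC array, genes below the remaining populations were 14 in the CX3CR1high macrophages, 5 in the CD11b+ cells and 14 in the CX3CR1- cells, and 31 were above them in the CX3CR1- cells.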

Other observations

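The single genes and immunoglobulin segments below were picked after their values were seen, and so were the tests of scaling, of muscle and endothelial genes and of the RNA ends, while the second epithelial and fibroblast lists were chosen without looking at their values. A scaling test of the epithelial list set beforehand, by equal medians or quantile normalization, was replaced by a later one, and its result is not given here. Lyve1, Folr2, Cd209f and Cbr2 were highest in the CX3CR1high macrophages. The hyaluronan receptor Lyve1 was at 5416 against 1725 in the CD11b+ cells, 455 in the CX3CR1- cells and 51.6 in the DCs. The folate receptor Folr2 stood at 7079, 1183, 364 and 100.3 in the same order, the lectin Cd209f at 1753, 259, 113 and 69.0, and Cbr2 at 7276, 1955, 498 and 27.4. The chemokines Ccl8, Ccl12 and Pf4 were also highest there, at 19869, 3031 and 24576. The costimulatory receptor Cd28 was at 732 in the CX3CR1high macrophages, 289 in the CD11b+ cells and under the floor in both others.

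In the CX3CR1- cells some genes had signals nearer to the DCs and others nearer to the CD11b+ cells or the CX3CR1high macrophages. Plet1, by the probe set used, was at 2603 in the CX3CR1- cells and 8253 in the DCs, and at 248 and 250.1 in the CX3CR1high macrophages and CD11b+ cells. The lectin-like receptors Klrd1 (2321 and 3933, against 223 and 187) and Klrb1b (2222 and 2591, against 279 and 123) were likewise higher in the CX3CR1- cells and the DCs. Acod1, which makes itaconate, was at 2819 in the CX3CR1- cells and 3289 in the CD11b+ cells, against 1092 in the CX3CR1high macrophages and 99.6 in the DCs. Retnla, a gene of macrophages exposed to interleukin 4 or 13, was at 27748 in the CX3CR1- cells, 13508 in the CD11b+ cells, 11955 in the CX3CR1high macrophages and 71.9 in the DCs. The collagenase Mmp13 was at 8837 in the CX3CR1- cells and 8835 in the CX3CR1high macrophages, against 1250.2 and 723 in the CD11b+ cells and DCs. Cd209d, like Cd209c and Cd209a, was highest in the CX3CR1- cells (342, against 128, 68.4 and 66.3 in the CX3CR1high macrophages, CD11b+ cells and DCs).

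Of 10 light chain variable segments of immunoglobulins above the floor in at least 1 array, 9 were lowest in the CX3CR1- cells. Igkv15-103 was at 294 there, against 3282 in the CX3CR1high macrophages, 4043 in the CD11b+ cells and 844 in the DCs. The exception was Igkv8-30, at 23809.7, 17292, 28556 and 12815 in the same order.

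Most epithelial markers were at least 2-fold higher in the CX3CR1high macrophages than in each other array. These were 12 of 12 members over the CD11b+ cells, 9 of 12 over the DCs and 8 of 13 over the CX3CR1- cells. Krt8 reached 6182 and Lgals4 2790.4 in the CX3CR1high macrophages. A gate on CD11b and CD11c selects against epithelial cells, but how fully it removed them was not measured here. The authors' scaling as the whole cause is argued against, since it moves all genes of an array alike. Median log2 ratios of all genes were -0.02, 0.02 and 0.02 over the CD11b+ cells, DCs and CX3CR1- cells. The epithelial median exceeded that of all genes by at least 1.27 in each comparison. As the arrays were already on a common scale, this gap largely restates the epithelial medians and adds little to them. A second list of 18 epithelial genes, with 0 in the first lists and 13 with a ratio, had 5, 9 and 4 members higher and medians of 0.97, 1.38 and 0.83 over the CD11b+ cells, DCs and CX3CR1- cells, with 6, 6 and 3 members as bounds and each median above the random range. The lowest of these lies between the bounds set beforehand for and against RNA from epithelial cells, and 5 of the 17 genes on the array were above the floor in every other array, so this source stays open. Uptake of epithelial cells by the macrophages, and expression by the population itself, were not tested and also stay open.

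Fibroblast genes were higher in the CD11b+ cells, where Col3a1 and Dcn reached 28325 and 15299, than in each other array. A gate on CD11b selects against fibroblasts, but how fully it removed them was not measured here. A higher share of all stromal cells alike is argued against, since the 8 muscle and endothelial genes of the same first list, whose values had been seen, had medians of -0.04 over the CX3CR1high macrophages and 0.22 over the CX3CR1- cells, although 1.10 over the DCs. A second list of 19 fibroblast genes, with 0 in the first lists and 18 on the array, had 16, 17 and 14 members higher and medians of 1.80, 3.53 and 1.30 over the CX3CR1high macrophages, DCs and CX3CR1- cells. RNA from fibroblasts is thus a candidate source that the values allow, and 10 of the 18 were above the floor in every other array too. Expression of these genes by CD11b+ cells was not tested and stays open.

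More genes were 4-fold below all others in the DCs (152) than in any other population. Some stromal genes were that far below, such as Sparc (297 against 1664 or more) and Acta2 (367 against 1558 or more). Others were less far apart, such as Col6a2 (464 against 1275 or more). How much of the count comes from less stromal RNA in the DC sample was not tested. Scaling as the whole cause is argued against, since with equal medians 107 genes were 4-fold below all others, against at most 7 in any other population. Less intact RNA is argued against by the ratio of 3' over 5' control signals, which was lowest in the DCs for Gapdh (0.791, against 1.08 to 3.40 in the others) and for Actb (1.115, against 1.68 to 3.18). The DCs also differ from the 3 other populations in being gated without CD11b, although the sample title of the CX3CR1- cells calls them DC as well. Whether a difference of cell type accounts for the count was not tested and stays open.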
